A study of Mus musculus with 6 samples.

How the data were processed

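RAW 264.7, a mouse macrophage cell line, was compared after 48 h with lipopolysaccharide (LPS, 100 ng/ml) plus LPS-binding protein (LBP, 100 pM) and after 48 h without treatment. LPS is an outer membrane component of Gram-negative bacteria, and LBP is the serum protein that carries it to its receptors. Total RNA of treated and untreated cells was labelled with Cy5 (red) or Cy3 (green) and hybridised together on 6 two-colour arrays, per the labels. On 3 arrays the treated RNA was in Cy5 and on the other 3 arrays it was in Cy3. Each orientation had arrays of set 1, set 2 and set 3.

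The authors deposited 1 log ratio per probe and array. The values were read as log2 ratios of Cy5 over Cy3. The base is not stated in the sources used here. Values up to 6.12 rule out log10, because such a ratio would exceed the range of a scanner, and a natural logarithm is not excluded, in which case every fold change given here would be larger. The labels name Cy5 as test and Cy3 as control, which gave the direction of the ratio. Arrays of opposite orientation correlated at -0.66 to -0.41 across probes and arrays of one orientation at 0.67 to 0.77, so the deposited ratios had not been turned. The sign also rests on the textbook LPS-induced genes Il1b, Il6, Tnf and Nos2, fixed before the data were examined, which were higher in treated cells on all 6 arrays under this reading. The direction reported below for these genes is therefore partly an input. Background correction, dye normalization, scanner and spot filters are not given in the sources used here. The deposited median log2 ratio was 0 on every array. No 2 arrays held identical values.

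Between 7.97% and 17.8% of values on an array were exactly 0, and 1011 of 16281 probes were 0 on all 6 arrays. A measured ratio is hardly ever exactly 0, so these values were treated as probable placeholders, and a probe with them is described as listed at 0. The analysis fixed before the data were examined kept them as values, and an alternative fixed at the same time set them to missing, which left 12724 probes with a value on all 6 arrays. Counts from both are given side by side.

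Probes were named through the platform's gene annotation. Of 16281 probes, 13738 had 1 gene symbol, 52 had several and 2491 had none. A mouse RefSeq gene table (GRCm38.p6) held 13694 of the 13738 by gene ID and changed 0 symbols. Probes with 1 symbol were averaged per array and symbol (avereps), giving 10698 genes, of which 2696 had over 1 probe. No genome build was named for the probes, so genomic positions were not used here.

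For the treatment effect, the sign of the 3 arrays with treated RNA in Cy3 was turned, the 2 orientations of each set were averaged so that a dye effect cancels, and the 3 set means were tested against 0 with limma (lmFit with an intercept and eBayes, two-sided). P-values were adjusted by the Benjamini-Hochberg method, and adjusted p under 0.05 counted as changed. The labels do not state that arrays of a set share RNA extracts. Counting a set as 1 replicate (n = 3) was the cautious choice. Errors are the SD of the 3 set means. A dye effect of each probe was tested in the same way on the set means of ratios that had not been turned. All per-sample columns were mapped to a sample, with 0 left over.

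The 23 gene lists were fixed before the data were examined. They covered cytokines and growth factors, chemokines, interferon-stimulated genes, inflammatory and antimicrobial effectors, the NF-kB pathway and its inhibitors, Toll-like receptors and LPS recognition, MHC class I antigen processing, MHC class II and costimulation, cell cycle and DNA replication, cell cycle inhibitors, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis, cholesterol synthesis, lipid handling and LXR targets, lysosome, osteoclast markers, antioxidant and metal response, unfolded protein response, apoptosis, macrophage identity, alternative activation, and markers of other cell types. Each was tested with limma's camera (preset inter-gene correlation of 0.01, and an estimated correlation) and fry, adjusted over the 23 lists. Camera compares a list with the other genes. With an estimated correlation its test relies on the 2 residual degrees of freedom of the 3 set means, which leaves it little power. Fry tests whether the members move, on balance, one way, and makes no comparison with other genes. For list members, p-values were also adjusted over the list alone. The text names the 12 largest increases and the 12 largest decreases among genes past the threshold with the same direction on all 6 arrays, skipping 44 placeholder names, then the 2 highest and the 2 lowest members of each list, and Cd14, Tlr4, Ly96, Lbp, Nos2, Tnf, Il1b and Il6.

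The procedure was tested on simulated ratios with the spread of these arrays and 200 changed probes, picked only among probes free of zeros. Noise was drawn independently for each array, whereas real arrays of a set shared deviations (consensus correlation 0.269 for probes). The 200 changed probes were also fewer than the 1407 called in the data. The shares recovered therefore compare settings and are not the power for these data. With zeros kept, it recovered 5.97% of simulated log2 changes of 0.5, 31.3% of changes of 1 and 47.0% of changes of 2 among 16281 probes, with 0 unchanged probes called. With zeros missing, it recovered 28.4%, 95.5% and 98.5% among 12724 probes, with 3 unchanged probes called. The loss of power came with the probes listed at 0 on all arrays, whose variance of 0 lowered limma's prior degrees of freedom to 0.760 for probes and 1.41 for genes, against 6.33 and 5.24 with zeros missing. A gene that did not pass is therefore not shown to be unchanged.

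Alternatives fixed before the data were examined were centring and scaling of the arrays, all 6 arrays as separate samples with or without a dye term, the set number as a random block, zeros missing, set means from any array present, robust moderation, a 2-fold minimum, 1 probe per gene, and leaving out each set or each array. The 1 probe kept per gene was that with the smallest SD over arrays. This rule prefers a probe listed at 0 on all arrays, whose SD is 0. After the data were seen, further alternatives left out the probes listed at 0 on all arrays, relaxed completeness with zeros missing, centred the arrays on values other than 0, set zeros to missing for the dye effect and the lists, and left out each set with zeros missing. R 4.3.3 with limma 3.58.1 was used, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9.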

Results

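The data were 6 two-colour arrays of 16281 probes, each setting treated against untreated RAW 264.7 macrophages within 1 hybridisation, 3 arrays per dye orientation. They address which transcripts differ after 48 h with LPS (100 ng/ml) and LBP (100 pM). The precision is limited by the number of arrays, and the number of calls also by the treatment of ratios listed at 0. Nothing in the labels states that the sets came from separate cultures, so the p-values measure the spread between these 3 set means, which may be technical. Values are log2 ratios of treated over untreated cells ± SD of the set means (n = 3), with the base of the logarithm taken as 2, and adjusted p-values are from limma. A gene said not to pass did not pass with zeros kept, and 13 such named genes passed with zeros missing. Calls of named genes come from the fit over genes. Some called genes with 1 probe did not pass in the fit over 16281 probes with zeros kept. Among them were Mki67, Tlr3, Acod1, Dcn and Tgfb1 (limma, adjusted p = 0.0503 to 0.0792).

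After 48 h of LPS and LBP, interferon-stimulated genes, cytokines and chemokines were among the largest increases. Of 71 genes of the cell cycle and DNA replication, 39 fell, by up to 1.09, and 2 rose. Rsad2, which encodes the antiviral protein viperin, rose by 4.33 ± 0.21 (20.1-fold). The monocyte chemoattractant Ccl2 rose 15.1-fold, the cytokine Il6 14.0-fold and the inflammasome product Il1b 11.5-fold. The direction of Il6 and Il1b had also been used to settle the sign of the ratio. Cd33, a sialic acid-binding lectin, fell by 1.99 ± 0.44 on the log2 scale and the IgG receptor Fcgr3 fell by 1.71 ± 0.16. Of 10698 genes, 942 rose and 634 fell, and 251 of the first and 35 of the second changed at least 2-fold. With zeros missing, 1310 of 9180 genes rose and 1089 fell. Both analyses called 1507 genes, 0 of them in opposite directions. A gene free of zeros has the same mean ratio in both, so its direction could not differ. Of the calls with zeros kept, 46 were lost with zeros missing and 23 could not be tested there.

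Without set 1, set 2 or set 3, limma called 1900, 1817 and 1728 genes with zeros missing. With zeros kept it called 0 genes in each case, with lowest adjusted p-values of 0.069, 0.123 and 0.0907 and with 2682, 2720 and 2674 genes at an unadjusted p under 0.05, against 3602 with all sets. With a set left out, the residual degrees of freedom fell below the 2 of all 3 set means. The prior degrees of freedom stayed low (1.31 to 1.52, against 1.41 with all sets). The 0s therefore do not show that the calls rest on any 1 set. Leaving out the single array with treated RNA in Cy5 of set 1 or set 2 gave 1024 or 906 genes, and leaving out that with treated RNA in Cy3 of set 2 or set 3 gave 613 or 823. When 1 array is left out, a dye effect no longer cancels in its set. Counts without 1 array, here and below, therefore do not reflect the loss of that array alone. At the level of probes, 903 rose and 504 fell, against 1887 and 1556 with zeros missing. Without set 1, 2 and 3 limma called 2692, 2230 and 2835 probes with zeros missing. With zeros kept it called 0 probes in each case, with lowest adjusted p-values of 0.169, 0.165 and 0.145 and with 3851, 3870 and 3878 at an unadjusted p under 0.05, against 5024 with all sets. Leaving out the array with treated RNA in Cy5 of set 2, or that with treated RNA in Cy3 of set 2 or set 3, gave 713, 429 or 724 probes. Of the changed probes, 171 had no symbol or several, 93 of them higher and 78 lower in treated cells.

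**Figure D1:**
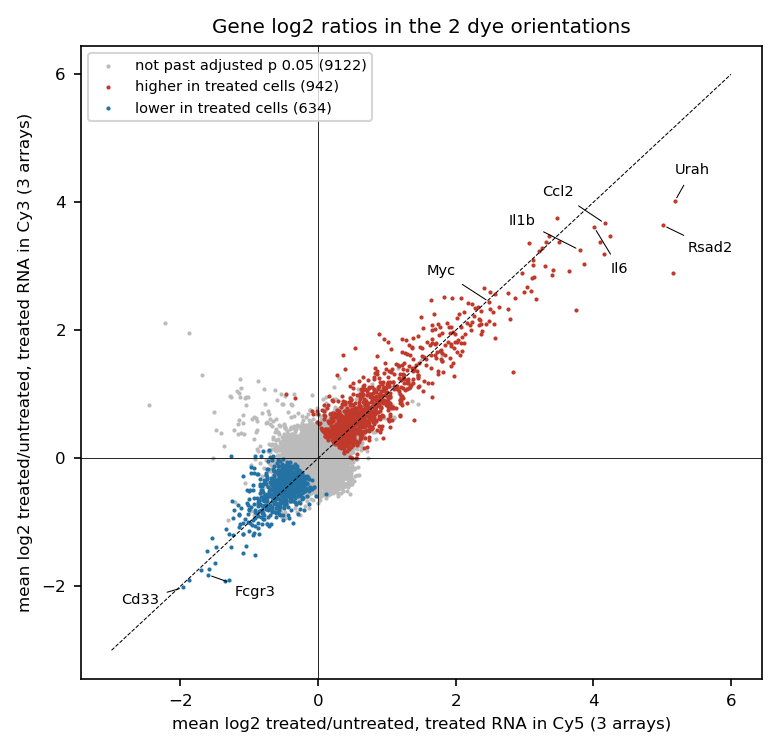
Each point is 1 of 10698 genes, with the mean log2 ratio of treated over untreated cells on the 3 arrays with treated RNA in Cy5 on the horizontal axis and on the 3 arrays with treated RNA in Cy3 on the vertical axis. Red points mark the 942 genes that rose, blue points the 634 that fell and grey points the rest; the dashed line marks equal values.

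The 12 largest increases included 4 genes of the interferon-stimulated list. Besides Rsad2 these were Ifi204 at 3.62 ± 0.06, the GTPase gene Gbp3 at 3.42 ± 0.40 (probes at 4.68 and 2.15) and the nucleotide kinase gene Cmpk2 at 3.34 ± 0.34. The largest mean ratio belonged to Urah, an enzyme of urate breakdown, at 4.60 ± 0.34 (24.2-fold, adjusted p = 0.0082) over 2 probes, at 5.36 and 3.83. Gene names are those of the platform annotation, and probe sequences were not available to check them. Ccl2 stood at 3.92 ± 0.15 (adjusted p = 0.00634), Gstt4, a glutathione transferase, at 3.86 ± 0.47 from 1 probe, Il6 at 3.81 ± 0.62 (adjusted p = 0.0162), the protein C receptor Procr at 3.67 ± 0.25, Il1b at 3.53 ± 0.30 (adjusted p = 0.0096), and Lcn2, which binds bacterial siderophores, at 3.45 ± 0.44. Ifi202b, a DNA-binding interferon-inducible gene, averaged 3.44 ± 0.20, but 2 of its probes gave 5.17 and 5.15 and the third gave 0.01.

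The 12 largest decreases were smaller in size. Besides Cd33 (adjusted p = 0.0231) and Fcgr3 (adjusted p = 0.0108), they held Klhl30 at -1.88 ± 0.29, the mitochondrial acetyl-CoA synthetase Acss1 at -1.72 ± 0.62, the tight junction gene Cldn11 at -1.66 ± 0.17, the carbonyl reductase Cbr2 at -1.60 ± 0.15, and the prostaglandin D synthase Ptgds at -1.53 ± 0.53. The paralogs Selenbp1 and Selenbp2, which are close in sequence, stood at -1.63 ± 0.48 and -1.57 ± 0.50. Caveolin Cav2 was at -1.43 ± 0.29, the DNA polymerase gene Dntt at -1.40 ± 0.48 and the guanylate cyclase Gucy2g at -1.32 ± 0.12. Being among these 24 genes required 1 direction on all 6 arrays. In the fit over probes with zeros kept, the single probes of Acss1, Selenbp1, Selenbp2, Ptgds and Dntt did not pass. Their adjusted p-values there were 0.0806, 0.0635, 0.0691, 0.0774 and 0.0758 (limma).

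**Figure D2:**
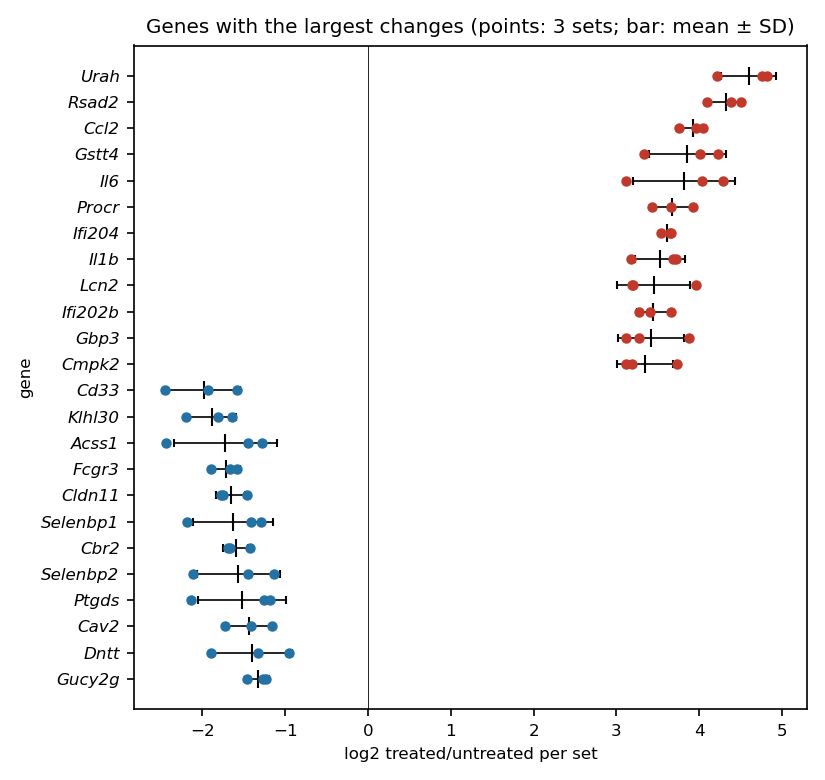
Log2 ratio of treated over untreated cells in each of the 3 sets (points; red higher, blue lower) for the 12 largest increases and the 12 largest decreases, with the mean (vertical mark) and SD (horizontal bar). The means run from 4.60 for Urah to -1.99 for Cd33.

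Interferon-stimulated genes formed the group with the highest median. Of 42 measured members, 36 rose and 0 fell (39 and 0 adjusted over the list alone), with a median log2 ratio of 1.95 (camera adjusted p = 5.09e-26, and adjusted p = 0.349 with an estimated correlation). Rsad2 and Ifi204 were highest. Isg20 was at 0.23 ± 0.22, with 1 array listed at 0, and did not pass, and Ly6e was listed at 0 on all arrays. The genes of MHC class I antigen processing, which load peptides for T cells, rose in 10 of 14 cases with 0 lower (11 and 0 adjusted over the list alone; camera adjusted p = 9.3e-08, and adjusted p = 0.218 with an estimated correlation). The peptide transporter Tap1 rose by 1.55 ± 0.08 and H2-T23 by 1.25 ± 0.05 (probes at 1.80 and 0.70), H2-M3 was at 0.19 ± 0.27 without passing, and Psme1 was listed at 0. In MHC class II and costimulation, 5 of 16 rose and 0 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.0307, and adjusted p = 0.349 with an estimated correlation). Its highest members were the checkpoint ligand Cd274 (1.70 ± 0.21) and the costimulatory receptor Cd40 (1.62 ± 0.12), and its lowest, H2-Oa (-0.21 ± 0.08) and Icosl (-0.24 ± 0.10), did not pass. Of the 2 probes of Icosl, 1 was listed at 0 on all arrays and the other, with 1 array at 0, gave -0.48 ± 0.21.

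Among cytokines and growth factors, 12 of 21 measured genes rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 1.18e-07, and adjusted p = 0.218 with an estimated correlation). Il6 and Il1b were highest, Tnf rose by 0.96 ± 0.18 (adjusted p = 0.0211), Tgfb1 fell by 0.64 ± 0.23 and Inhba was at -0.04 ± 0.09 without passing. Of 20 chemokines, 9 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 1.89e-04, and adjusted p = 0.277 with an estimated correlation). Ccl2 led them, followed by Cxcl11 at 2.21 ± 0.09, whose 2 probes gave 3.00 and, with 1 array listed at 0, 1.41, whereas Cxcl9 (-0.08 ± 0.11, with 1 of 2 probes listed at 0) and Cxcl14 (-0.18 ± 0.32) did not pass. Inflammatory and antimicrobial effectors rose in 18 of 33 cases with 0 lower (22 and 1 adjusted over the list alone; camera adjusted p = 1.94e-07, and adjusted p = 0.349 with an estimated correlation). Lcn2 led, Acod1, which makes itaconate, rose by 3.04 ± 0.95 with 1 array listed at 0, and the inducible nitric oxide synthase Nos2 rose by 1.11 ± 0.18 (adjusted p = 0.0175). The lowest members, the oxidase subunit Ncf4 (-0.15 ± 0.16) and tissue factor F3 (-0.29 ± 0.08, adjusted p = 0.0504), did not pass.

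In the NF-kB pathway and its inhibitors, 16 of 30 genes rose and 1 fell (19 and 1 adjusted over the list alone; camera adjusted p = 1.26e-06, and adjusted p = 0.218 with an estimated correlation). The adaptor Traf1 rose by 1.76 ± 0.17 and the repressor Atf3 by 1.74 ± 0.28, the kinase Irak1 fell by 0.40 ± 0.13, and Socs3 was at -0.22 ± 0.25 without passing. Toll-like receptors and LPS recognition genes went both ways, 3 of 12 higher and 2 lower (4 and 2 adjusted over the list alone), and were not distinguished from other genes as a group (camera adjusted p = 0.26, and fry adjusted p = 0.0204, upward). Tlr3, a receptor for double-stranded RNA, rose by 1.81 ± 0.45 and Tlr1 by 1.15 ± 0.13, while Tlr2, the receptor for bacterial lipoproteins, fell by 1.24 ± 0.28 and the LPS receptor Tlr4 fell by 0.43 ± 0.12 (adjusted p = 0.0409). Of the 3 probes of Tlr4, those free of zeros gave -0.70 and -0.67 and the other 0.09. The LPS co-receptor Cd14 was at 0.01 ± 0.06 (adjusted p = 0.871) and Lbp at 0.07 ± 0.02 (adjusted p = 0.284). Lbp read 0.16, 0.54 and 0.21 with treated RNA in Cy5 and -0.01, -0.35 and -0.12 in Cy3. Its small SD therefore does not show a precise value. The sign of Inhba and Socs3 also differed between orientations in every set. Ly96, the partner of Tlr4, averaged 0.64 ± 0.33 (adjusted p = 0.0803), with 1 of 2 probes listed at 0 on all arrays and the other at 1.28 ± 0.66. With zeros missing Ly96 passed (limma, adjusted p = 0.00498).

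Genes of the cell cycle and DNA replication fell in 39 of 71 cases and rose in 2 (49 and 2 adjusted over the list alone; 50 and 2 of 68 with zeros missing), with a median of -0.44 (camera adjusted p = 1.26e-12, downward, and adjusted p = 0.382 with an estimated correlation). The lowest were the microtubule regulator Stmn1 at -1.09 ± 0.20 and the proliferation marker Mki67 at -1.01 ± 0.23. The 2 that rose were the transcription factor Myc, by 2.47 ± 0.03 (5.53-fold), and the cyclin Ccnd2, by 0.54 ± 0.11. Cell cycle inhibitors rose in 6 of 17 cases and fell in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0472, and adjusted p = 0.349 with an estimated correlation). Cyclin Ccng1 rose by 0.86 ± 0.02 and Gadd45b by 0.69 ± 0.18, the retinoblastoma-like Rbl1 fell by 0.58 ± 0.20, and the inhibitor Cdkn1b was at -0.29 ± 0.35 without passing. This list's camera call was lost without any 1 of the sets (adjusted p = 0.0728 to 0.0974) and with zeros missing (adjusted p = 0.0666).

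**Figure D3:**
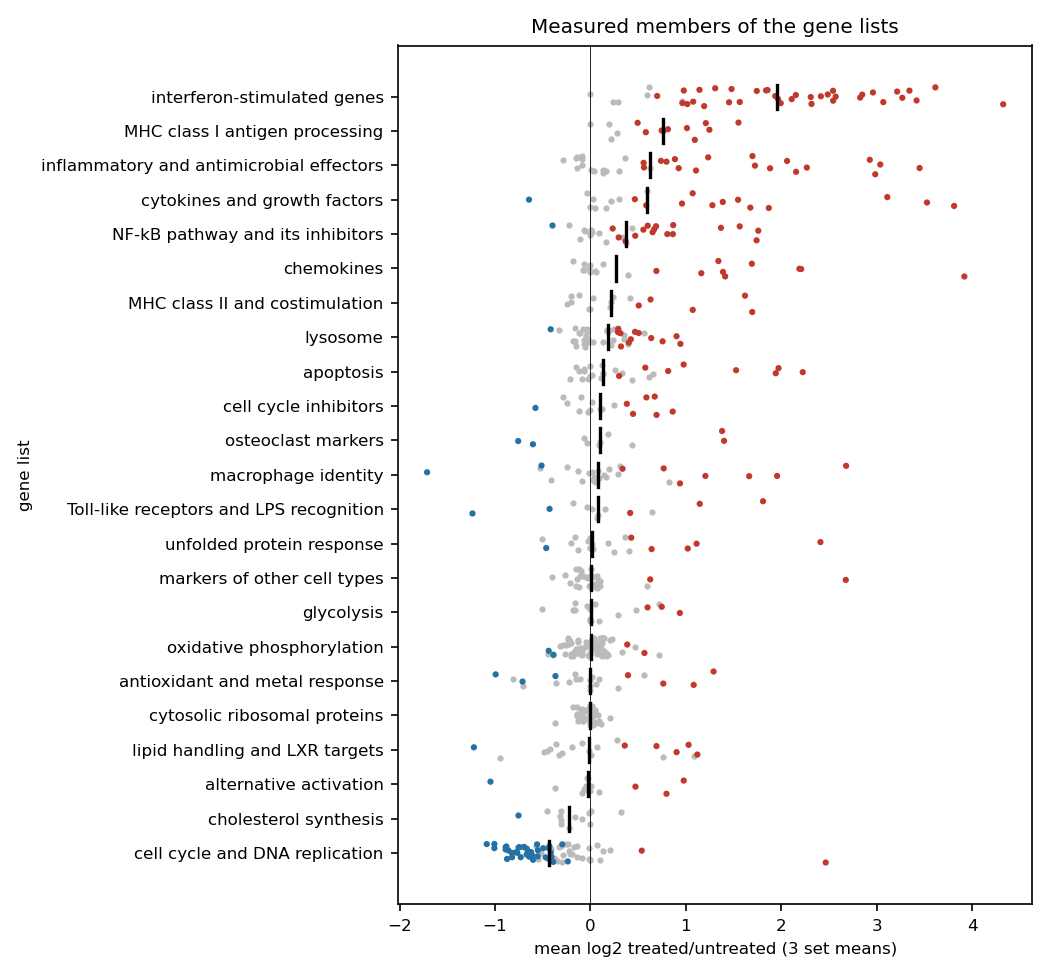
Each point is a measured member of a gene list, placed by its mean log2 ratio of treated over untreated cells over 3 set means; red members rose, blue members fell, grey members did not pass, and the black mark is the list's median. The median runs from 1.95 for interferon-stimulated genes to -0.44 for cell cycle and DNA replication.

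Of 27 apoptosis genes, 8 rose and 0 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.00211, and adjusted p = 0.374 with an estimated correlation). The death receptor Fas rose by 2.23 ± 0.08 and Bcl2a1a, an inhibitor of apoptosis, by 1.97 ± 0.10, and Bcl2 (-0.15 ± 0.10) and Bbc3 (-0.22 ± 0.05) did not pass. Lysosomal genes rose in 12 of 44 cases and fell in 1 (15 and 3 adjusted over the list alone; camera adjusted p = 0.00313, and adjusted p = 0.383 with an estimated correlation). The lysosomal membrane protein gene Lamp2 rose by 0.94 ± 0.08 and Lamp1 fell by 0.42 ± 0.10. The galactosidase Gla rose by 0.90 ± 0.07, and Arsb was at -0.32 ± 0.11 without passing. Among macrophage identity genes, 7 of 29 rose and 2 fell (9 and 3 adjusted over the list alone; 9 and 4 of 28 with zeros missing; camera adjusted p = 0.0173, and adjusted p = 0.349 with an estimated correlation). The receptor kinase Axl rose by 2.68 ± 0.36 and the high-affinity IgG receptor Fcgr1 by 1.96 ± 0.15. The low-affinity IgG receptor Fcgr3 fell, and Csf1r, the receptor for colony-stimulating factor, was at -0.53 ± 0.22 without passing (adjusted p = 0.0609). With zeros missing Csf1r passed (limma, adjusted p = 0.00926).

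Camera did not distinguish the other lists from the remaining genes. Glycolysis had 3 of 18 genes higher and 0 lower (3 and 0 adjusted over the list alone; 5 and 1 of 13 with zeros missing; camera adjusted p = 0.182), with 3 listed at 0. The glucose transporter Slc2a1 rose by 0.94 ± 0.22 and the regulator Pfkfb3 by 0.75 ± 0.11, and Pfkl (-0.18 ± 0.41) and Aldoc (-0.50 ± 0.35) did not pass. Oxidative phosphorylation had 2 of 73 higher and 2 lower (0 and 0 adjusted over the list alone; 4 and 5 of 65 with zeros missing; camera adjusted p = 0.965). Ndufa13 rose by 0.57 ± 0.09, Atp5k fell by 0.44 ± 0.15, and Cox6a2 (0.72 ± 0.43) and Uqcrh (-0.44 ± 0.27) did not pass. In cholesterol synthesis 1 of 13 fell, Sqle by 0.76 ± 0.12, and 0 rose (1 and 0 adjusted over the list alone; 3 lower of 12 with zeros missing; camera adjusted p = 0.0973). That camera test passed downward with zeros missing (adjusted p = 0.0461) and without set 3 (adjusted p = 0.00507). Msmo1 was at -0.46 ± 0.30, Tm7sf2 at 0.32 ± 0.34 and Pmvk at 0.00 ± 0.10. Lipid handling and LXR targets had 5 of 21 higher and 1 lower (8 and 8 adjusted over the list alone; 6 and 7 of 17 with zeros missing; camera adjusted p = 0.916). The fatty acid transporter Cd36 rose by 1.12 ± 0.18 and the fatty acid synthase Fasn fell by 1.22 ± 0.13, while Lpl (1.08 ± 0.56) and Apoc2 (-0.95 ± 0.59) did not pass. Lpl and Apoc2 passed with zeros missing (limma, adjusted p = 0.00589 and 0.012).

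Antioxidant and metal response genes went both ways, 4 of 22 higher and 3 lower (4 and 5 adjusted over the list alone; camera adjusted p = 0.916), with 3 listed at 0. The haem oxygenase Hmox1 rose by 1.29 ± 0.24 and the metallothionein Mt2 by 1.08 ± 0.29, the glutathione synthesis gene Gclc fell by 0.99 ± 0.16, and Txnrd1 was at -0.81 ± 0.36 without passing. Txnrd1 passed with zeros missing (limma, adjusted p = 0.00473). The unfolded protein response had 5 of 20 higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.144, and fry adjusted p = 0.017, upward). The stress-induced transcription factor Ddit3 rose by 2.41 ± 0.25 and Chac1 by 1.11 ± 0.09, Xbp1 fell by 0.46 ± 0.12, and Sdf2l1 was at -0.50 ± 0.45 without passing. Its probes gave 0.10 and -1.11, and the second read -2.95, -3.02 and -3.01 with treated RNA in Cy5 but was listed at 0 on 2 arrays and read 2.32 on the third with treated RNA in Cy3. Of 10 osteoclast markers, 2 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.406). These were the phosphatase Acp5 (1.40 ± 0.33) and the cell-cell fusion factor Ocstamp (1.38 ± 0.14) upward, and Nfatc1 (-0.60 ± 0.14) and Car2 (-0.76 ± 0.20) downward. Alternative activation had 3 of 14 higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.893), with Egr2 rising by 0.98 ± 0.31, Tgm2 rising by 0.80 ± 0.07, Gas6 falling by 1.05 ± 0.38 and Clec10a at -0.37 ± 0.39 without passing. Among 31 markers of other cell types, 2 rose and 0 fell (1 and 0 adjusted over the list alone; 3 and 1 of 27 with zeros missing; camera adjusted p = 0.916). They were the fibroblast proteoglycan Dcn, by 2.68 ± 0.95, and the B cell receptor component Cd79a, by 0.63 ± 0.11. The lowest, Cd8a (-0.41 ± 0.36, with probes at 0.06 and, with 1 array listed at 0, -0.87) and Alb (-0.26 ± 0.08), did not pass.

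Cytosolic ribosomal protein genes gave little information. Limma called 0 of 66 higher and 0 lower (0 and 0 adjusted over the list alone; 0 and 1 of 23 with zeros missing; camera adjusted p = 0.915), but 30 of them were listed at 0 on all arrays. Rpl41 was at 0.21 ± 0.08, Rpl35a at 0.11 ± 0.14 with 3 arrays listed at 0, Rps20 at -0.19 ± 0.41 and Rpl27a at -0.37 ± 0.20.

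Over the 23 lists, camera with the preset correlation called 11 upward and 1 downward, and 0 of these calls held with an estimated correlation (adjusted p = 0.218 to 0.383). That loss does not show that correlation between genes accounts for the calls, since the second test had 2 residual degrees of freedom. The estimate was below the preset 0.01 for some called lists, such as cytokines (-0.0195) and NF-kB (-0.0135). It was above 0.01 for others, such as interferon-stimulated genes (0.355) and cell cycle (0.321). Fry called 14 lists in 1 direction and 22 as changed in either direction. Mean and median differed in sign for lipid handling (0.07 and -0.02), for alternative activation (0.04 and -0.03) and, close to 0, for oxidative phosphorylation (-0.00906 and 0.00153), and for antioxidant genes camera pointed downward and fry upward.

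The dye effect, a probe's departure from 0 once the treatment cancels, was called for 0 of 16281 probes by limma with zeros kept, with 3922 at an unadjusted p under 0.05. With zeros missing it was called for 23 of 12724 probes, and with the 6 arrays as separate samples for 44.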

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

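The dye comparison with zeros missing was chosen after the data were seen. With zeros set to missing, 23 probes differed between the 2 dye orientations (limma, adjusted over 12724 probes), where a ratio without dye effect would only change its sign. All 23 were lower in Cy5 than in Cy3 whichever RNA the dye carried, by log2 values from -2.48 to -0.65, and 18 of them by at least 2-fold. With the 6 arrays as separate samples and zeros kept, the direction was mixed, with 8 of 44 called probes higher in Cy5 and 36 lower. None of the 23 was called for treatment with zeros kept (0 of 23). Among them, picked after their values were seen, were Gabrr1 at -2.48, Mmp20 at -2.24, Nek4 at -2.21 and Ifi30 at -2.17. The list members Il12a and Ctsk had a probe with dye effects of -1.10 and -2.14. No biological explanation was tested.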

How the results depend on the processing

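Leaving out probes at 0, relaxing completeness, centring on values other than 0, leaving out sets with zeros missing, and setting zeros to missing for the dye effect and the lists were chosen after the data were seen. The number of calls changed with the settings. Of the 76 named genes past the threshold, 0 turned direction in the 25 settings run for genes, whereas 9 named genes not past it, among them Cd14, Pmvk and Inhba, turned in at least 1. For the called genes this was largely fixed in advance. Apart from Acod1 and Rbl1, all 76 had 1 direction on all 6 arrays, and leaving out arrays cannot turn such a gene. That direction was required of the 12 largest changes each way. Cxcl9, Icosl and Ly96, whose means over probes were not 0, stood at 0 with 1 probe per gene. Each had a probe listed at 0 on all arrays, which the smallest-SD rule picks. Ly6e and Psme1, with a single probe each, were listed at 0 from the start. Of the lists past camera's threshold 0 turned direction, and 5 others did: ribosomal proteins and oxidative phosphorylation without set 3, lipid handling with the 6 arrays separate, with the replicate block and without set 2, antioxidant genes without set 2 and markers of other cell types without set 1. Against 1407 probes and 1576 genes, limma called 4037 probes and 2986 genes with the 6 arrays as separate samples and a dye term, 3525 and 2658 without that term, 3443 and 2399 with zeros missing, 3153 and 2373 without probes at 0 on all arrays, and 346 and 286 with a 2-fold minimum. Scaling gave 656 probes and 1166 genes. Relaxed completeness with zeros missing gave 3046 probes. With zeros missing and without set 1, set 2 or set 3, 2692, 2230 and 2835 probes passed. Leaving out 1 set or 1 array gave 0 to 1371 probes and 0 to 1446 genes, with 0 for each whole set left out with zeros kept, where the prior degrees of freedom for genes were 1.31 to 1.52 against 6.97 to 10.3 with zeros missing. The set number as a replicate block gave 3393 probes and 2513 genes. Deviations of arrays with the same set number correlated at 0.08 to 0.53. Those of arrays with other set numbers across orientations correlated at -0.35 to 0.13, so the ranges overlap. Of 6 arrays, 5 correlated best with their own number, a hint from the data and not from the design. Of the 76 named genes past the threshold, 66 kept the call after scaling, 59 with 1 probe per gene and 58 without the array of set 2 with treated RNA in Cy3. Acss1 and Ptgds missed it in 10 of 25 settings and Dntt in 9, including the 3 without a set in which no gene passed. With zeros missing, 13 of the 108 named genes with a value gained the call and 0 lost it, whereas over all genes 892 gained it and 46 lost it. The named genes that gained it were Ly96, Csf1r, Txnrd1, Lpl, Apoc2, Cox6a2, Uqcrh, Msmo1, Aldoc, F3, Arsb, Rpl27a and Cd8a. Centring on the median and set means from any array present changed nothing, since medians were 0 and no value was missing. The dye effect rose from 0 probes to 44 with the 6 arrays separate (8 higher and 36 lower in Cy5) and 23 with zeros missing.

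With an estimated correlation, camera's adjusted p was 0.218 for cytokines, NF-kB and MHC class I, 0.277 for chemokines, 0.349 for interferon-stimulated genes, effectors, MHC class II, cell cycle inhibitors and macrophage identity, 0.374 for apoptosis, 0.382 for cell cycle and 0.383 for lysosome. That test had 2 residual degrees of freedom, so these values do not show that the lists are unchanged. With the preset correlation, the adjusted p of cell cycle inhibitors rose from 0.0472 to 0.0537 without and 0.055 with the replicate block, 0.0687 after scaling, 0.0666 with zeros missing and 0.0728 to 0.0974 without a set. With that correlation cholesterol synthesis passed with zeros missing (0.0461) and ranged from 0.00507 to 0.257 without a set. Apart from the effect of the zeros on moderation, the cause was not tested. Spot intensities were not used here, so limits from dim signal cannot be given.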

Other observations

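All tests in this part were chosen after the data were seen, except the count of regrouped arrays, the probe comparison by accession and the check of zeros among disagreeing probes. Genes were grouped by the stem of their symbol, and 518 stems with at least 4 measured genes were tested for an excess of changed genes over the background of 10698 (Fisher's exact test, one-sided, adjusted over the stems in each direction). The Schlafen genes, which are in none of the fixed lists, stood out. Of 5 measured genes with that stem 4 rose (adjusted p = 0.0288), among them Slfn1 by 3.15 ± 0.19 and Slfn3 by 3.13 ± 0.28 (SD of 3 set means). Of 13 Ms4a genes, which encode membrane proteins of leukocytes, 6 rose and 0 fell (adjusted p = 0.0339), Ms4a4c by 3.19 ± 0.42 and Ms4a6d by 1.93 ± 0.28. Of 13 dual-specificity phosphatase genes (Dusp) 6 rose and 1 fell (adjusted p = 0.0339), led by Dusp1 at 1.37 ± 0.30. Genes of the mouse MHC (stem H2) rose in 16 of 32 cases and fell in 1 (adjusted p = 9.29e-07), Ifi genes rose in 6 of 8 and fell in 0 (adjusted p = 0.00285), Gbp genes rose in 4 of 5 and fell in 0, and genes with the stem Il rose in 15 of 61 and fell in 3 (adjusted p = 0.0288 for both), and these groups overlap with the fixed lists. Genes with 1 stem may be close in sequence, which was not checked, so their probes cannot be taken as independent of each other.

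The stems with an excess of lower genes were 2. Of 10 Lsm genes, which encode RNA-binding proteins of splicing and mRNA decay, 5 fell and 0 rose (adjusted p = 0.0366), Lsm2 by 0.58 ± 0.09 and Lsm3 by 0.50 ± 0.13. Of 9 Mcm genes, helicase components of DNA replication, 5 fell and 0 rose (adjusted p = 0.0366), but 7 of the 9 are in the fixed lists. Of the Dusp and Ms4a genes 2 and 1 are in those lists, and of the Lsm genes 0.

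Within the cell cycle list, mitotic genes averaged -0.61 ± 0.27 (SD over 26 genes, 17 lower) and DNA replication genes -0.41 ± 0.23 (28 genes, 16 lower). The difference was -0.20, and -0.15, -0.23 and -0.21 in the 3 sets. It was not tested, since an exact sign-flip test over 3 sets cannot give a two-sided p under 0.25. Whether cells had left the cycle at a given phase was not measured.

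The ratios listed at exactly 0 were not spread evenly. Independent spot defects would leave 0.026 probes at 0 on all 6 arrays, against 1011 observed, which argues against them as the main source. Ribosomal protein probes had 58.7% of their values at 0, against 8.5% of other named probes (Fisher's exact p = 1.87e-16 on probes with any 0). This is what loss of very bright spots would give, and such a loss may explain part of the zeros. Markers of other cell types, whose spots should be dim, had 8.91% at 0 (Fisher's exact p = 0.56), too few probes to decide whether dim spots were lost too. Probes with no gene symbol had 24.7% at 0, which leaves other sources open.

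Probes of 1 gene mostly gave similar ratios, with exceptions. Among changed genes with at least 2 probes free of zeros, the median absolute difference was 0.18 for 55 pairs from 1 accession and 0.16 for 356 pairs from different accessions, so noise between spots could account for the typical difference. In 18 of 340 such genes, however, 1 probe had a mean ratio of at least 2-fold either way and another lay within 0.25 of 0, among them Ifi202b, Fabp4 (3.11 and 0.19), Ccl22 (2.53 and 0.24), Adm (2.29 and -0.03) and Il4i1 (2.12 and -0.03). The count rests on size alone. The 2-fold probes of Rassf8 and Rnf112 did not pass (limma, adjusted p = 0.0626 and 0.0557). The probe of Adm at -0.03 is also 1 of the 23 with a dye effect (-1.12), and Adm is the only 1 of the 18 genes with such a probe. These probes held no zeros, so zeros did not pull them down. When such pairs were picked on set 1 alone among all genes, which gave 33 pairs of 29 genes, 17 of the 18 among them, the gap had the same direction on average over sets 2 and 3 in all 33. Its median there was 0.891 of the gap in set 1, which argues against noise of single spots. A wrong clone or name of 1 probe remains open: 19 of the disagreeing pairs came from different accessions and 1 from the same, which the test did not tell apart from the shares among all pairs (Fisher's exact p = 0.496).

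Regrouping the 6 arrays into 3 and 3 allows 10 splits, too few for a share under 0.05. With the 6 arrays as separate samples the real split gave 2986 genes and 4037 probes, and the highest of the others gave 0 genes and 3 probes, so 1 of 10 splits reached the real count for each. In the other splits a real treatment effect adds to the residual spread of the fit, so few calls there were fixed in advance. The contrast therefore does not measure how often regrouping alone gives such counts.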
